A study of Rattus norvegicus with 48 samples.

How the data were processed

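RNA was measured by sequencing in 48 libraries from 24 female Long-Evans rats. From each animal a retina library and a library of the posterior eye, the back of the eye around the retina, were made. Ovariectomy (OVX) removes the ovaries and with them most circulating oestrogen, and sham surgery leaves the ovaries in place. Age and surgery gave 4 groups of 6 animals, here called young sham, young OVX, aged sham and aged OVX. Young animals were 3 to 4 months old and the older animals, called middle-aged by the submitters and aged here, were 9 to 10 months old. Each library was assigned to its group and animal from its own label.

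Per the labels' protocols, cDNA was made from a small amount of total RNA with the SMART-Seq kit, a low-input method that amplifies full-length cDNA, fragmented with Nextera XT and sequenced as paired ends on an Illumina NovaSeq. The protocol describes no strand-marking step, so reads of overlapping and antisense genes can be mixed. The authors deposited 1 table of whole-number read counts per gene for each tissue, and the values summed to different totals per library, as raw counts do. The submitters' processing notes name STAR 2.7.3a, an aligner, HTSeq, a read counter, DESeq2, a test of differential expression, and the rat genome build Rnor_6.0, without saying how each was set. The annotation and the counting options are not given in the sources used here. Genes are named as in the tables and no coordinates are printed, since no annotation of that build was used here. Members of gene families with near-identical copies, such as the haemoglobin and major histocompatibility genes, are uncertain, because the counting could split their reads.

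Each table held 32883 genes, of which 25248 in the posterior eye and 24809 in the retina had at least 1 count. For the posterior eye, 25 gene names had been turned into calendar dates. These genes stayed in the posterior eye totals and tests, are not named, and were left out of the fit across tissues. Low counts were removed with edgeR's filterByExpr, which left 16401 genes in the posterior eye, 15481 in the retina and 17153 across both tissues. Total counts per library had a median of 18266453 in the posterior eye and 17937769.5 in the retina. The common biological coefficient of variation was 33.4% in the posterior eye and 12% in the retina, so the same fold change was estimated less precisely in the posterior eye at similar depth. Col1a2 had almost no counts in any posterior eye library while Col1a1 was abundant, so Col1a2 was not tested. Several matrix, muscle and interferon genes of the lists were not in the tables and were not analysed here.

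The main test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, a negative binomial model with 1 mean per group over all 24 libraries of a tissue, and the quasi-likelihood F test. Contrasts were OVX against sham within each age, their mean over both ages, aged against young within sham and within OVX, and the interaction of OVX and age. A fit over all 48 libraries tested whether the OVX effect differed between tissues. P-values were two-sided and adjusted over all genes tested by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Fold changes are given on the log2 scale with their standard errors, and levels as CPM, counts relative to the TMM-scaled library total on the standard scale of edgeR, with the SD over 6 libraries. Each standard error was derived as the absolute log2 fold change divided by the square root of F, so it is approximate.

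A total of 44 gene lists for matrix, signalling, immune, retinal, vascular, metabolic and neighbouring-tissue genes were tested with camera of limma 3.58.1 on the log2 values, with the preset correlation of 0.01 between genes, and adjusted over the lists of each contrast. Camera was repeated with an estimated correlation. Fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, was also run. For each list the number of members above and below 0 and the number called when adjusted over the list alone were counted. The level of a list in a library was its mean log2 CPM, and 6 libraries were set against 6 with an exact permutation test over 924 splits, whose smallest p is 0.00216.

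Genes were named by a rule. For each OVX contrast and for ageing in sham animals, called genes at 2 CPM or more in the higher group were ranked by p and up to 10 in each direction with non-provisional symbols were named. Where fewer than 5 passed, the 5 with the smallest p were given as values. Up to 4 members of each called list were added, with 5 in each direction for the interaction and the tissue difference. Esr1, Esr2, Gper1, Pgr, Col1a1, Col1a2, Col3a1, Col4a1, Fn1, Dcn, Lox, Mmp2, Timp1, Tgfb1 and Gfap were among the genes always reported where tested, and some genes the rule names are left out of the text. The groups, tests, lists and the rule for named genes were fixed before the data were examined. A list of sebaceous gland markers was added after the data were seen.

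Posterior eye and retina libraries with the same animal number come from the same animal, as the titles of the labels state. Over 10861 genes, the deviations of the 24 same-animal pairs from their group means correlated with a median Spearman correlation of 0.0385, between -0.111 and 0.461, against a median of 0.00589 over 120 pairs of different animals of a group. The fit across tissues was repeated with the animal as a block.

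Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE scaling, no filter on low counts, a fit of only the groups compared, surrogate variables from sva 3.50.0 (3 in the posterior eye and 5 in the retina), a neighbouring-tissue covariate (the level of rod genes in the posterior eye and of pigment epithelium genes in the retina), leaving out each library in turn, and leaving out the posterior eye libraries of animals 22 and 23, whose library numbers, 66 and 69, hold another place among their animal's numbers than in the other animals. For each contrast 100 groupings of the libraries were tested, the real one included, and 40 for the tissue difference.

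The steps were tested on simulated counts with 100 genes changed at each of 2 fold sizes. For young OVX against sham, 37% of genes changed 1.5-fold and 75% of those changed 2-fold were recovered in the posterior eye, and 69% and 82% in the retina. For the interaction the shares were 8% and 42% in the posterior eye and 63% and 72% in the retina. No recovered gene had the wrong direction and 0 of 44 unchanged lists were called. The simulated genes varied independently and the unchanged lists held random genes. So the list count does not show how often camera calls an unchanged list whose genes vary together. The changed genes were simulated all at once, which loosens the adjusted threshold compared with real contrasts that called few genes. Varying amounts of tissue were not simulated. The recovered shares may therefore be higher than the real data would allow. Beside the recovered genes, 5 unchanged genes were called for young OVX, 11 for aged OVX and 9 for the OVX mean in the posterior eye, and 7, 3 and 10 in the retina.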

Results

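The data were read counts per gene in retina and posterior eye from 24 female Long-Evans rats, with 6 animals in each of the young sham, young OVX, aged sham and aged OVX groups. The question posed by the design is how loss of the ovaries changes gene expression in each tissue, whether age alters that response, and whether it involves the extracellular matrix. Depth ran from 11470945 to 22971367 counts per library in the posterior eye and from 12916146 to 30737547 in the retina. Posterior eye libraries held mixed tissue. Rpe65, the isomerase of the visual cycle in the retinal pigment epithelium, averaged 307.1 CPM there against 20.48 in the retina, on the scale of the fit over both tissues, and Col1a1, the main chain of type I collagen, 1868 against 1.318. The mean level of rod genes ranged from 2 to 9.21 log2 CPM between posterior eye libraries and from 10.5 to 10.8 between retina libraries. Awat2, a wax synthase of sebaceous and meibomian glands, ranged from 0.05367 to 1457 CPM in the posterior eye. Library numbers run in order of group, so order of handling is confounded with group.

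In the young posterior eye, OVX was compared with sham to ask what loss of the ovaries does in young adults. Mthfd1l, a mitochondrial enzyme of one-carbon metabolism, rose from 14.8 ± 2.11 to 23.9 ± 3.55 CPM (SD, n = 6 per group), a log2 fold change of 0.69 ± 0.10 (SE) with an adjusted p of 0.00668, and was higher in 6 of 6 OVX libraries than the sham median. It was the 1 gene called of 16401 tested. Among the next genes by p, Wee1, a kinase that restrains entry into mitosis, was at 35.5 ± 6.55 CPM in sham and 54.6 ± 9.16 in OVX (adjusted p = 0.273). The immediate early gene Fos was at 42.1 ± 12.3 and 17.1 ± 3.12 CPM (adjusted p = 0.432), and Siglec10, a sialic acid receptor of immune cells, at 6.04 ± 2.17 and 1.56 ± 0.65 (adjusted p = 0.273). Lonrf3 had a log2 fold change of 0.72 ± 0.17 (adjusted p = 0.521). The Mthfd1l call was lost when only the 2 groups were fitted, with the sebaceous gland level as a covariate and with surrogate variables, where 0 genes were called. A total of 1023 genes had an unadjusted p under 0.05, where 820 are expected with no effect.

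The strongest list in that contrast was cholesterol synthesis and uptake. All 24 measured genes lay lower in young OVX, with a median log2 fold change of -0.457 (camera adjusted p = 4.91e-20). Called members numbered 0 over all genes and 19 when adjusted over the list alone. Mvd, which makes isopentenyl diphosphate, was at 41.1 CPM in sham and 24.6 in OVX (log2 -0.74 ± 0.20), Idi1 at 31.9 and 20.7 (-0.63 ± 0.16) and Fdps at 305 and 220 (-0.47 ± 0.14), each with an adjusted p of 0.661 over all genes. The adjusted p was 0.397 with an estimated correlation. Immediate early genes also lay lower as a set, 25 of 26 below 0, with a median of -0.292 (adjusted p = 7.22e-10; 5 called when adjusted over the list alone and 0 over all genes). Egr1 was at 106 CPM in sham and 45.6 in OVX. The list had an adjusted p = 0.373 with an estimated correlation. The sebaceous gland level in the same libraries was 3.42 ± 3.13 log2 CPM in sham and 1.16 ± 1.16 in OVX (SD, n = 6; exact permutation p = 0.128).

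Extracellular matrix genes lay slightly higher as a set in the young OVX posterior eye. Of 183 measured, 135 were above 0, with a median log2 fold change of 0.155 (camera adjusted p = 1.35e-06). No member was called, over all genes or when adjusted over the list alone (0 and 0), and the list had an adjusted p = 0.756 with an estimated correlation. Basement membrane genes had 21 of 25 above 0 and a median of 0.20 (adjusted p = 3.19e-06; 0 called when adjusted over the list alone; adjusted p = 0.756 with an estimated correlation). Col4a1, a chain of the type IV collagen of basement membranes, was at 105.7 ± 12.3 CPM in sham and 137.7 ± 27.3 in OVX (log2 0.38 ± 0.14, adjusted p = 0.718), and Adamts1, a secreted protease, at 109 and 153 CPM (0.48 ± 0.12, adjusted p = 0.661). No abundant stromal gene was called. Col1a1 had a log2 fold change of 0.02 ± 0.24, Col3a1 of -0.37 ± 0.31, Fn1, encoding fibronectin, of 0.10 ± 0.13, Lox, a collagen crosslinking enzyme, of -0.06 ± 0.20 and Mmp2, a matrix protease, of -0.01 ± 0.17. Dcn, encoding the proteoglycan decorin, was at 3046 ± 427 and 3631 ± 919 CPM. The mean level of the matrix list per library was 5.41 ± 0.20 log2 CPM in sham and 5.5 ± 0.16 in OVX (n = 6 each, exact permutation p = 0.403).

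Other tissue components moved in the same contrast. All 13 melanocyte genes (median 0.384, adjusted p = 3.07e-06) and all 18 endothelial genes (0.233, adjusted p = 0.000146) lay higher, as did 20 of 24 myelin and Schwann cell genes (0.437, adjusted p = 0.00141) and all 21 lens genes (0.749, adjusted p = 0.00518). Each of these had an adjusted p = 0.756 with an estimated correlation. Adjusted over the list alone, 4 lens genes were called and 0 of the other 3 lists. The lens level spread 29.5-fold between posterior eye libraries. The melanosome protein Pmel was at 1280 CPM in sham and 1790 in OVX. Rod genes lay lower, 28 of 30 below 0 with a median of -0.295 (adjusted p = 0.00348; adjusted p = 0.797 with an estimated correlation; 0 called when adjusted over the list alone). With the rod level as a covariate the matrix list had an adjusted p of 0.00358, and with rod and sebaceous levels together the matrix list had an adjusted p of 0.464.

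In the aged posterior eye no gene was called between OVX and sham by edgeR, against 422 at an unadjusted p under 0.05, 27 called by DESeq2 and 0 by limma-voom. The smallest p belonged to Fzd5, a WNT receptor, at 6.07 ± 0.74 CPM in sham and 3.69 ± 0.47 in OVX (log2 -0.71 ± 0.14, adjusted p = 0.881). Pdyn, encoding prodynorphin, was at 7.63 ± 2.81 and 18.8 ± 3.83 CPM (1.31 ± 0.29, adjusted p = 1). Matrix genes were centred near 0, with 112 of 183 above 0, a median of 0.0382 and a mean of -0.00755, which differ in sign (camera adjusted p = 0.587, 0 called when adjusted over the list alone). Col1a1 was at 1166 ± 363 CPM in sham and 1201 ± 530 in OVX, and Tgfb1 at 15.5 ± 2.78 and 19.6 ± 4.23. All 29 interferon response genes lay higher in OVX, with a median of 0.263 (adjusted p = 4.54e-07, 0 called when adjusted over the list alone; adjusted p = 0.944 with an estimated correlation). Ifi27 was at 361 CPM in sham and 475 in OVX, and Bst2 at 23.6 and 30.4. Circadian clock genes lay lower, 13 of 17 below 0 with a median of -0.147 (adjusted p = 4.17e-05, 0 called when adjusted over the list alone; adjusted p = 0.232 with an estimated correlation). Ciart, a clock repressor, was at 33.0 and 21.5 CPM and Dbp, a clock output factor, at 294 and 237. Rod genes lay below 0 in 30 of 30 cases, with a median of -0.471 (adjusted p = 0.0156; adjusted p = 0.944 with an estimated correlation).

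Averaged over both ages, no posterior eye gene was called by edgeR, with 938 at an unadjusted p under 0.05, 67 called by DESeq2 and 4 by limma-voom. Mthfd1l (log2 0.41 ± 0.07), Siglec10 (-1.54 ± 0.27) and Gnaq, a G protein subunit (0.27 ± 0.05), each had an adjusted p of 0.0695. Of 44 lists, 24 were called by camera and 0 with an estimated correlation. The matrix list had 125 of 183 genes above 0 and a median of 0.0922 (adjusted p = 0.00014, 0 called when adjusted over the list alone; adjusted p = 0.678 with an estimated correlation). Rod genes lay lower beside it, 30 of 30 below 0 with a median of -0.417 (adjusted p = 0.00014; adjusted p = 0.678 with an estimated correlation).

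Whether age changed the OVX effect in the posterior eye was asked with the interaction. No gene was called by edgeR, with 487 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. All 24 cholesterol genes had a positive interaction, with a median of 0.592 (adjusted p = 2.37e-21, 10 called when adjusted over the list alone and 0 over all genes; adjusted p = 0.222 with an estimated correlation). Idi1 was at 31.9, 20.7, 27.9 and 35.2 CPM in young sham, young OVX, aged sham and aged OVX. This contrast includes the young groups, and carried-over sebaceous gland was not separated from an effect of OVX for the cholesterol genes. Immediate early genes had 25 of 26 above 0, with a median of 0.369 (adjusted p = 1.31e-09, 1 called when adjusted over the list alone; adjusted p = 0.205 with an estimated correlation). The matrix list had 131 of 183 below 0 and a median of -0.113 (adjusted p = 0.000455, 0 called when adjusted over the list alone; adjusted p = 0.996 with an estimated correlation).

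**Figure D1:**
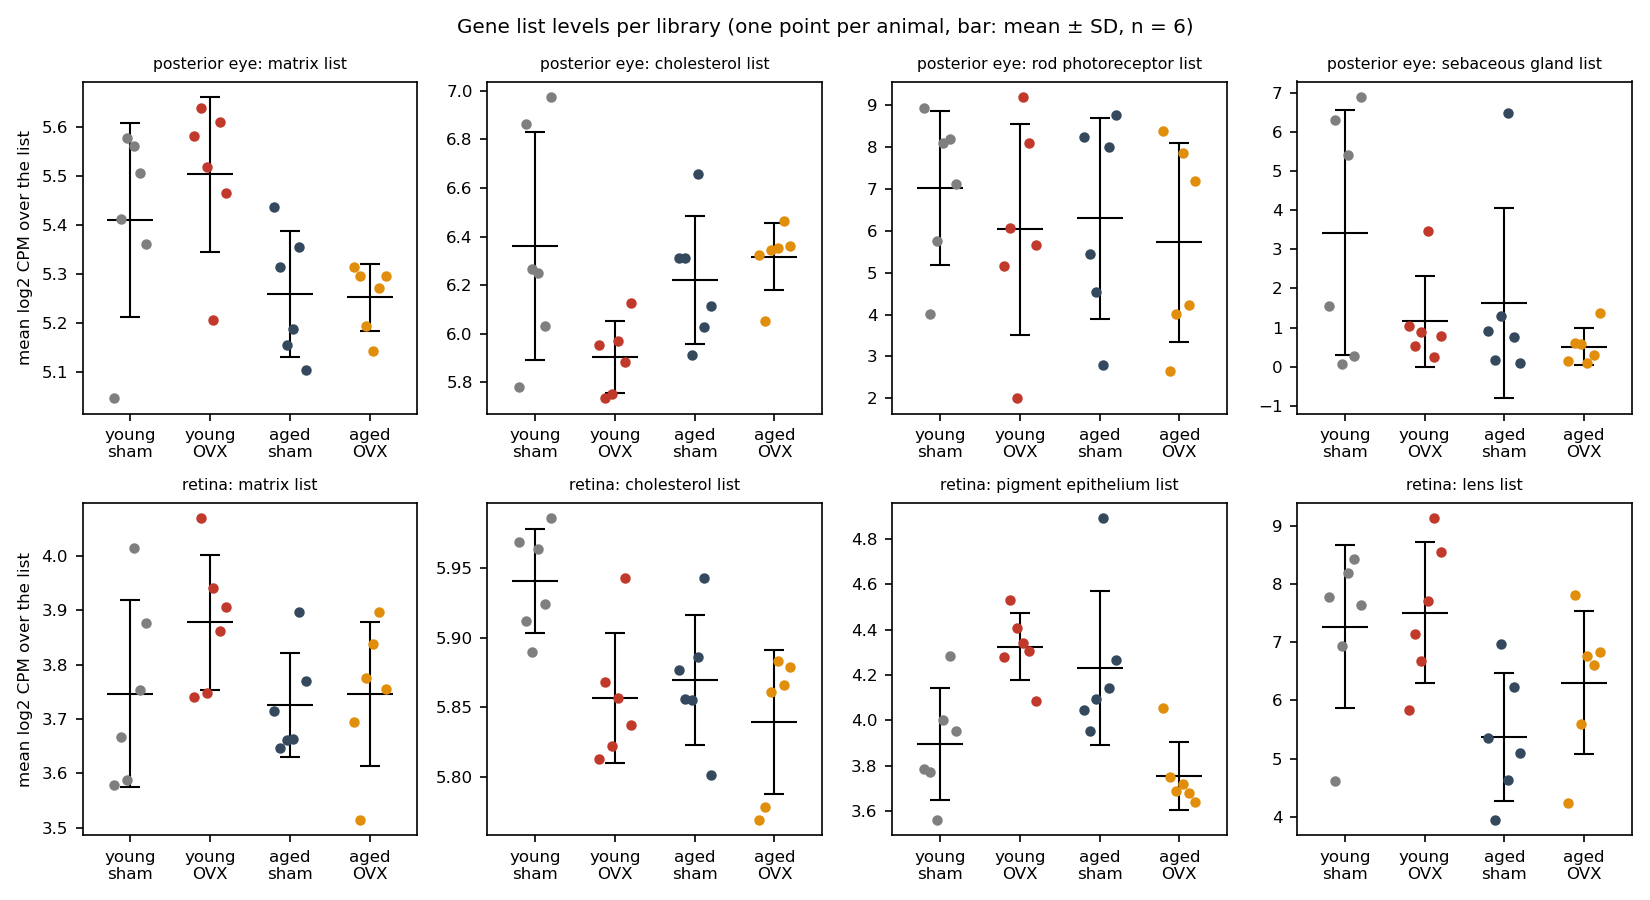
Mean log2 CPM of 4 gene lists per library in the posterior eye (top) and 4 in the retina (bottom); each point is 1 animal and bars are mean ± SD of 6 animals in young sham, young OVX, aged sham and aged OVX. Posterior eye matrix levels overlap between young sham (5.41 ± 0.20) and young OVX (5.5 ± 0.16), the rod and sebaceous gland levels scatter widely within each group, and the retinal pigment epithelium level is 3.89 ± 0.25 and 4.32 ± 0.15 in young sham and OVX and 4.23 ± 0.34 and 3.76 ± 0.15 in aged sham and OVX.

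In the young retina 3 of 15481 genes were called between OVX and sham. Tfeb, a transcription factor that drives lysosomal genes, rose from 11.2 ± 0.83 to 15.0 ± 1.13 CPM (SD, n = 6 per group; log2 0.42 ± 0.07). Coq10b, a mitochondrial coenzyme Q binding protein, rose from 26.3 ± 2.23 to 34.9 ± 3.85 CPM (0.41 ± 0.07). Pfkp, a phosphofructokinase of glycolysis, fell from 343.5 ± 19.7 to 297.0 ± 7.20 CPM (-0.21 ± 0.04). Each had an adjusted p of 0.0322 and all 6 OVX libraries on the same side of the sham median. Tonsl (0.46 ± 0.09, adjusted p = 0.0747) and Nab2 (0.45 ± 0.09, adjusted p = 0.0925) followed. When only the 2 groups were fitted, Tfeb, Coq10b and Pfkp lost their calls and 3 other genes were called. DESeq2 called 60 genes and limma-voom 9, with 3 shared in both cases. The edgeR test called 0 with the pigment epithelium level as a covariate, with surrogate variables and without the filter on low counts. It also called 0 without any 1 of the libraries of young sham animals 1, 2 and 6 or young OVX animals 8, 9 and 10. Over all 12 runs with 1 library left out, Tfeb and Coq10b were called in 3 each and Pfkp in 1.

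Pigment epithelium genes formed the strongest list in the young retina. Of 24 measured, 21 lay higher in OVX, with a median of 0.422 (camera adjusted p = 4.48e-08; 9 called when adjusted over the list alone and 0 over all genes; adjusted p = 0.381 with an estimated correlation). Rgr, a photoisomerase of the pigment epithelium and Müller glia, was at 35.2 ± 11.9 CPM in sham and 67.99 ± 18.3 in OVX, and Rpe65 at 16.8 ± 5.13 and 29.7 ± 7.43. Cholesterol genes lay lower, 20 of 24 below 0 with a median of -0.0865 (adjusted p = 1.95e-05, 5 called when adjusted over the list alone; adjusted p = 0.381 with an estimated correlation). Fdft1, encoding squalene synthase, was at 175 CPM in sham and 158 in OVX (-0.15 ± 0.04, adjusted p = 0.16). Interferon response genes had 27 of 28 above 0 and a median of 0.236 (adjusted p = 0.00978, 0 called when adjusted over the list alone; adjusted p = 0.677 with an estimated correlation).

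Matrix genes in the young retina had 111 of 162 above 0 and a median of 0.103 (camera adjusted p = 0.0037; 0 called over all genes and 0 when adjusted over the list alone; adjusted p = 0.677 with an estimated correlation). Fibrillar and associated collagens had 17 of 20 above 0 and a median of 0.263 (adjusted p = 0.000723, 0 called when adjusted over the list alone; adjusted p = 0.381 with an estimated correlation). Col8a1, a short-chain collagen, was at 14.7 CPM in sham and 22.7 in OVX (0.62 ± 0.20, adjusted p = 0.227), and Col6a2 at 9.63 and 14.4 (0.57 ± 0.23, adjusted p = 0.339). Adamts1 had the opposite sign, at 51.4 and 41.5 CPM (-0.31 ± 0.09, adjusted p = 0.181). Col4a1 was at 344 ± 149 and 379 ± 98.0 CPM. With the pigment epithelium level as a covariate the adjusted p was 0.18 for the matrix list and 0.0539 for the collagens. Without the library of young OVX animal 8 the matrix list had an adjusted p of 0.0994.

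In the aged retina 1 gene was called. Myoc, encoding the secreted glycoprotein myocilin, fell from 23.3 ± 11.7 CPM in sham to 6.31 ± 2.24 in OVX (log2 -1.87 ± 0.30, adjusted p = 0.0322, lower in 6 of 6). The call was lost without any 1 of the libraries of aged sham animals 13 and 16 and aged OVX animals 20 to 24, with adjusted p up to 0.162, with the pigment epithelium level as a covariate, with surrogate variables and with limma-voom. When only the 2 groups were fitted, Myoc lost its call and 1 other gene was called. Ttr, encoding the retinol carrier partner transthyretin, was at 146.4 ± 90.5 and 50.5 ± 13.7 CPM (-1.53 ± 0.29) and Rgr at 63.4 ± 31.7 and 23.9 ± 8.00 (-1.41 ± 0.27), with adjusted p of 0.113 for both. Pigment epithelium genes as a set had 19 of 24 below 0 and a median of -0.40 (adjusted p = 8.38e-11; 13 called when adjusted over the list alone and 0 over all genes; adjusted p = 0.383 with an estimated correlation). Oxidative phosphorylation genes had 36 of 42 below 0 with a median of -0.0409 (adjusted p = 6.48e-05, 0 called when adjusted over the list alone; adjusted p = 0.798 with an estimated correlation), and Sdha, a succinate dehydrogenase subunit, was at 437 and 414 CPM. Lens genes had 21 of 22 above 0 with a median of 1.05 (adjusted p = 0.000258; adjusted p = 0.798 with an estimated correlation), and the lens filament gene Bfsp1 was at 11.3 and 62.9 CPM. The lens level spread 36.4-fold between retina libraries, and a varying amount of carried-along lens was not separated from an effect of OVX. The matrix list had a median of 0.0283 (adjusted p = 0.629, 0 called when adjusted over the list alone). Its adjusted p was 0.0248 without the library of aged OVX animal 20.

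The OVX effect in the retina differed between ages in 7 genes by the interaction test, 6 negative and 1 positive. Myoc (log2 -2.76 ± 0.41, adjusted p = 0.00895), Rgr (-2.36 ± 0.38, adjusted p = 0.0127), Ttr (-2.42 ± 0.40, adjusted p = 0.0138), Pon1, encoding paraoxonase (-2.52 ± 0.43, adjusted p = 0.0181), and Rpe65 (-2.09 ± 0.39, adjusted p = 0.0406) had higher means in OVX than sham at the young age and lower means at the older age. Tf, encoding transferrin (-1.53 ± 0.29, adjusted p = 0.0479), and the provisional LOC102555924 (1.80 ± 0.33, adjusted p = 0.0321) complete the 7 and were named after their values were seen. Ttr was at 85.3 ± 33.2, 157.6 ± 40.6, 146.4 ± 90.5 and 50.5 ± 13.7 CPM in young sham, young OVX, aged sham and aged OVX (n = 6 each). Pigment epithelium genes as a set had 21 of 24 interactions below 0 and a median of -0.867 (camera adjusted p = 2.46e-19), with 3 called over all genes and 15 when adjusted over the list alone. This was the 1 list called in any contrast that held with an estimated correlation (adjusted p = 0.0407; fry adjusted p = 0.0131). With 1 library left out, that adjusted p ran from 0.0115 without aged sham animal 16 to 0.0975 without aged OVX animal 23. Melanocyte genes had 10 of 13 below 0 with a median of -0.653 (adjusted p = 0.000226, 5 called when adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). Myoc, Rgr, Ttr and Pon1 were called in 24 of 24 runs with 1 library left out and Rpe65 in 9 of 24. With the pigment epithelium level as a covariate no interaction was called by edgeR, and the log2 values were -1.27 for Myoc and -0.91 for Pon1. Rgr, Ttr and Rpe65 are part of that level, so their values with it are not informative.

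**Figure D2:**
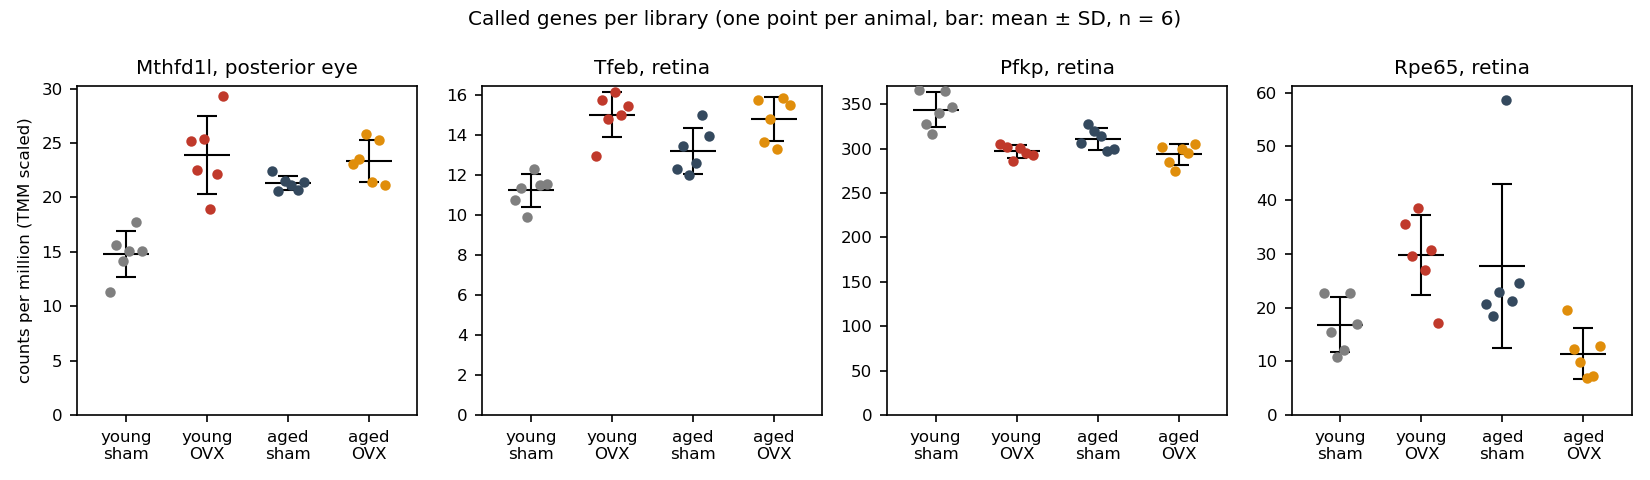
TMM-scaled CPM per library for Mthfd1l in the posterior eye and Tfeb, Pfkp and Rpe65 in the retina; each point is 1 animal and bars are mean ± SD of 6 animals per group, with axes from 0. Mthfd1l is at 14.8 ± 2.11 in young sham and 23.9 ± 3.55 in young OVX, and Rpe65 is at 16.8 ± 5.13 and 29.7 ± 7.43 in young sham and OVX but 27.7 ± 15.3 and 11.4 ± 4.67 in aged sham and OVX.

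Averaged over both ages, OVX changed 8 retinal genes, 4 in each direction, of which 5 are named here. Tfeb (log2 0.29 ± 0.05) and Nab2, a corepressor of early growth response factors (0.34 ± 0.06), rose, and Pfkp fell (-0.15 ± 0.03), each with an adjusted p of 0.0348. Stx3, the syntaxin of ribbon synapses (-0.14 ± 0.03, adjusted p = 0.0478), and Slc20a1, a phosphate transporter (-0.125 ± 0.02, adjusted p = 0.0481), fell. These 5 were called in 3 to 11 of 24 runs with 1 library left out. With the pigment epithelium level as a covariate 9 genes were called, including all 8, and with surrogate variables 87, including 5 of the 8. RLE scaling kept 7 and no filter on low counts kept 6, and Stx3 and Slc20a1 were among those lost. Matrix genes had 119 of 162 above 0 and a median of 0.0733 (adjusted p = 0.00686, 0 called when adjusted over the list alone; adjusted p = 0.876 with an estimated correlation). Collagen processing and crosslinking genes had 24 of 25 above 0 and a median of 0.0814 (adjusted p = 0.00293, 0 called when adjusted over the list alone; adjusted p = 0.75 with an estimated correlation). The matrix call was lost without young sham animal 3 (adjusted p = 0.0523) or young OVX animal 8 (0.0657).

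Oestrogen receptor transcripts were low in both tissues. In the young posterior eye Esr1, encoding oestrogen receptor alpha, was at 4.74 ± 0.51 CPM in sham and 5.55 ± 0.88 in OVX, Esr2 at 0.98 ± 0.47 and 0.99 ± 0.37, Gper1 at 3.50 ± 0.44 and 3.98 ± 1.79 and Pgr at 1.02 ± 0.35 and 1.07 ± 0.56. In the young retina Esr1 was at 2.16 ± 0.44 and 1.88 ± 0.55 and Esr2 at 2.29 ± 0.47 and 1.82 ± 0.30. None was called. The list of oestrogen receptors and response genes was not called in either tissue, with adjusted p of 0.644 in the young posterior eye and 0.63 in the young retina and 0 called when adjusted over the list alone. The gliosis marker Gfap had log2 fold changes of 0.94 ± 0.93 in the young posterior eye and -0.20 ± 0.20 in the young retina.

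Ageing was examined by comparing aged with young sham animals. In the posterior eye no gene was called by edgeR, with 481 at an unadjusted p under 0.05, 5 called by DESeq2, 0 by limma-voom and 11 by edgeR with surrogate variables. Among the smallest p were those of Mthfd1l (14.8 ± 2.11 CPM in young and 21.3 ± 0.65 in aged), Eln, encoding elastin (81.2 ± 11.1 and 49.2 ± 7.77), and the glucocorticoid target Fkbp5 (29.3 ± 6.27 and 45.7 ± 5.68), each with an adjusted p of 0.176. Matrix genes lay lower with age, 136 of 183 below 0 with a median of -0.101 (adjusted p = 9.07e-07; 3 called when adjusted over the list alone and 0 over all genes; adjusted p = 0.889 with an estimated correlation). Fibrillar collagens had 18 of 21 below 0 and a median of -0.253 (adjusted p = 1.43e-06, 1 called when adjusted over the list alone; adjusted p = 0.365 with an estimated correlation). Col1a1 was at 2357 ± 382 CPM in young and 1166 ± 363 in aged sham (log2 -1.02 ± 0.24, adjusted p = 0.77), Col3a1 at 880 ± 377 and 448 ± 196, and Sparc, a collagen-binding matrix protein, at 2040 and 1290. Lens genes had 19 of 21 below 0 and a median of -1.15 (adjusted p = 2.84e-06, 3 called when adjusted over the list alone; adjusted p = 0.889 with an estimated correlation), and rod genes had 27 of 30 below 0 (adjusted p = 0.028; adjusted p = 0.889 with an estimated correlation). Varying amounts of lens and retina in these samples were not separated from an effect of age.

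In the retina 6 genes were called between aged and young sham. Plvap, which forms the diaphragms of fenestrated vessels, rose from 7.17 ± 0.75 to 11.5 ± 1.97 CPM (log2 0.68 ± 0.11, adjusted p = 0.0115), and the RNA-binding protein gene Igf2bp2 fell from 29.7 ± 2.97 to 18.0 ± 2.48 (-0.73 ± 0.11, adjusted p = 0.0115). Tonsl, a DNA repair scaffold (0.50 ± 0.09), and Rnf207 (0.54 ± 0.10) rose and the bicarbonate transporter gene Slc4a7 fell (-0.34 ± 0.06), with an adjusted p of 0.0245 each, and Coro6 rose (0.52 ± 0.10, adjusted p = 0.0474). All 6 aged libraries lay on the same side of the young median for each gene. No gene was called without young sham animal 4 or aged sham animal 16 or with the pigment epithelium level as a covariate. Only Igf2bp2 and Slc4a7 kept their calls with surrogate variables, and 24 genes were called without aged sham animal 13. Over 12 runs with 1 library left out, Igf2bp2 was called in 10, Plvap in 9, Tonsl, Rnf207 and Slc4a7 in 3 each and Coro6 in 2. DESeq2 called 59 genes with all 6 shared, limma-voom 6 with 4 shared, and a fit of only the 2 groups 4 with 3 shared. Interferon response genes had 27 of 28 above 0 and a median of 0.413 (adjusted p = 1.92e-06, 0 called when adjusted over the list alone; adjusted p = 0.39 with an estimated correlation), and antigen presentation genes 13 of 14 and 0.279 (adjusted p = 7.5e-05, 2 called when adjusted over the list alone; adjusted p = 0.342 with an estimated correlation). B2m, the light chain of class I molecules, was at 41.9 and 52.5 CPM. Basement membrane genes had 18 of 24 below 0 (adjusted p = 7.5e-05, 11 called when adjusted over the list alone and 0 over all genes; adjusted p = 0.407 with an estimated correlation). Col4a1 was at 344 ± 149 and 163 ± 71.6 CPM (-1.08 ± 0.28, adjusted p = 0.155). Lens genes lay lower beside them, 21 of 22 below 0 with a median of -1.62 (adjusted p = 1.49e-09, 17 called when adjusted over the list alone; adjusted p = 0.39 with an estimated correlation), and so did 17 of 18 skeletal muscle genes, with a median of -0.864 (adjusted p = 0.000287, 9 called when adjusted over the list alone; adjusted p = 0.534 with an estimated correlation). Between retina libraries the lens level spread 36.4-fold and the skeletal muscle level 7.65-fold. A varying amount of carried-along tissue was not separated from an effect of age for these lists or the basement membrane genes.

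Within OVX animals, ageing changed 11 retinal genes and no posterior eye gene by edgeR, where 1663 had an unadjusted p under 0.05, DESeq2 called 93, limma-voom 75 and edgeR with surrogate variables 272. In the retina Ccdc61, a centriole protein gene, rose (log2 0.50 ± 0.07, adjusted p = 0.00738), Myoc fell (-1.92 ± 0.30, adjusted p = 0.00992), and Coro6 (0.58 ± 0.10) and Plvap (0.61 ± 0.11) rose while Ttr (-1.64 ± 0.29) and Igf2bp2 (-0.63 ± 0.11) fell, each with an adjusted p of 0.019. All 6 aged OVX libraries lay on the same side of the young OVX median for these 6 genes. With 1 library left out, Ccdc61 and Myoc were called in 12 of 12 runs, Coro6 in 8, Ttr in 7, Plvap in 6 and Igf2bp2 in 5. The pigment epithelium level was 4.32 ± 0.15 log2 CPM in young OVX and 3.76 ± 0.15 in aged OVX, a difference of -0.57 (exact permutation p = 0.00216, adjusted p = 0.208). With that level, of which Ttr is a part, as a covariate 2 genes were called, 0 of them among the 11. With surrogate variables 20 were called, 4 of them among the 11, with Myoc and Ttr kept and Ccdc61, Coro6, Plvap and Igf2bp2 lost. In the posterior eye the matrix list had 161 of 183 genes below 0 and a median of -0.227 (adjusted p = 6.82e-15; 10 called when adjusted over the list alone and 0 over all genes; adjusted p = 0.331 with an estimated correlation), and cholesterol genes had 23 of 24 above 0 and a median of 0.426 (adjusted p = 1.55e-15, 15 called when adjusted over the list alone; adjusted p = 0.331 with an estimated correlation). Lens genes had 21 of 21 below 0 beside them, with a median of -2.27 (adjusted p = 1.37e-09, 18 called when adjusted over the list alone; adjusted p = 0.331 with an estimated correlation). The lens level spread 29.5-fold between posterior eye libraries. Varying amounts of lens or sebaceous gland tissue were not separated from an effect of age.

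The OVX effect was then compared between tissues over both ages. Gnaq, which couples receptors to phospholipase C, differed by 0.40 ± 0.06 on the log2 scale, posterior eye minus retina (adjusted p = 0.00162), and was the 1 gene called of 17153. In the posterior eye Gnaq was at 24.9 ± 1.72, 30.7 ± 2.17, 23.6 ± 2.40 and 27.95 ± 1.53 CPM in young sham, young OVX, aged sham and aged OVX. Its OVX mean in the posterior eye alone was smaller, from 0.249 to 0.295 with 1 library left out. The difference of 0.40 need not come from the posterior eye alone, and retina levels of Gnaq are not given here. Adamts1 (0.50 ± 0.11, adjusted p = 0.239) and Far2, a fatty acyl reductase of sebaceous glands (-4.48 ± 1.00, adjusted p = 0.31), came next. By camera 7 of 44 lists were called. The OVX effect was lower in the posterior eye for rod (adjusted p = 0.000416), ganglion cell (0.00596), bipolar cell (0.00798), cholesterol (0.00798), amacrine and horizontal cell (0.0152) and ribosomal genes (0.0367), and higher for pigment epithelium genes (0.0152). Each had an adjusted p = 0.976 with an estimated correlation. The rod level spread 148-fold between posterior eye libraries and 1.18-fold between retina libraries. For the lists of retinal cells, a varying amount of retina in the posterior eye samples was not separated from a response to OVX. The sebaceous gland level spread 114-fold between posterior eye libraries and 2.17-fold between retina libraries. For cholesterol genes and Far2 a varying amount of gland was likewise not separated. The matrix list had an adjusted p of 0.623.

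Across the 16401 genes of the posterior eye, which are not independent replicates, the OVX effects at the older age correlated with those at the young age with a Pearson r of 0.446 and a Spearman rho of 0.281, and 57.1% of genes had the same sign. Of 100 groupings of the libraries, the real one included, 20 gave an r as large in absolute value (range of the others -0.592 to 0.753). In the retina r was 0.0292 and rho 0.0904, and 82 of 100 groupings gave an r as large in absolute value (range of the others -0.243 to 0.281).

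Levels of the lists were also compared library by library. Of 352 exact permutation tests, 40 had an unadjusted p under 0.05 where 17.6 are expected, and 0 remained after adjustment (smallest adjusted p = 0.208). The retinal pigment epithelium level in the retina was 3.89 ± 0.25 log2 CPM in young sham and 4.32 ± 0.15 in young OVX (exact permutation p = 0.00649), and 4.23 ± 0.34 and 3.76 ± 0.15 in aged sham and OVX (exact permutation p = 0.00649). Of 7 relations between list levels over 24 libraries, with group means removed, the sebaceous gland and cholesterol levels in the posterior eye had a Pearson r of 0.699 (permutation p = 0.00884, adjusted p = 0.0309) and a Spearman rho of 0.512 (permutation p = 0.0417, adjusted p = 0.146), with r at 0.529 without the 2 libraries farthest from the median. Pigment epithelium and melanocyte levels in the retina, whose lists share Tyr, Tyrp1 and Pmel, had an r of 0.611 (permutation p = 0.00513, adjusted p = 0.0309) and a rho of 0.504 (permutation p = 0.0169, adjusted p = 0.118), with r at 0.416 without the 2 farthest. Rod and matrix levels in the posterior eye had an r of -0.154 (permutation p = 0.484, adjusted p = 0.592) and a rho of 0.00304 (permutation p = 0.989). Sebaceous gland and matrix levels there had an r of -0.201 (permutation p = 0.507, adjusted p = 0.592) and a rho of -0.275 (permutation p = 0.261).

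**Figure D3:**
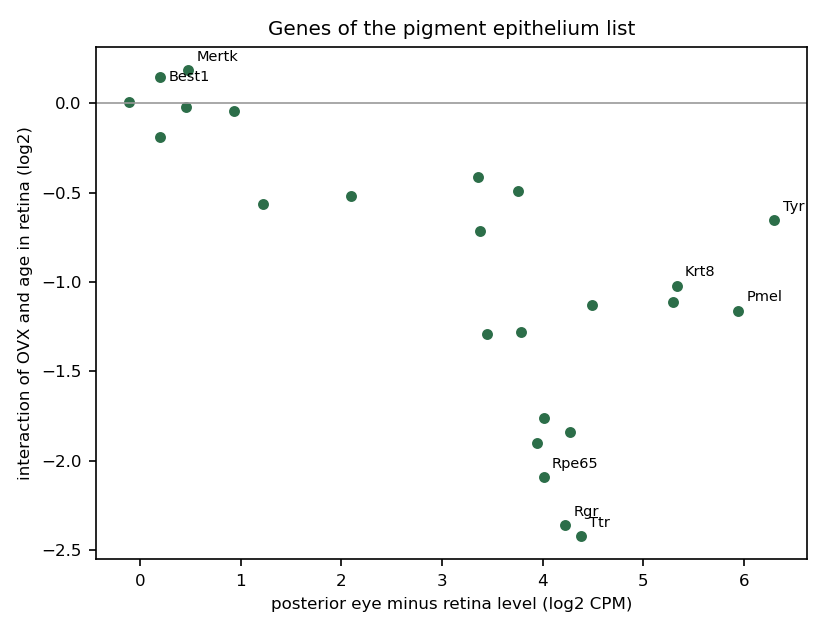
Each point is 1 of the 24 genes of the pigment epithelium list; the x axis is the posterior eye level minus the retina level (log2 CPM) and the y axis the interaction of OVX and age in the retina (log2). Genes far more abundant in the posterior eye, such as Rpe65 (4.01) and Ttr (4.38), have interactions of -2.09 and -2.42, Tyr (6.3) and Pmel (5.94), with the largest excess, have -0.653 and -1.16, and Best1 (0.198) and Mertk (0.477) have 0.149 and 0.184.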

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

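The test of pigment epithelium abundance given here was chosen only after the result was seen. Of 137 groups of 6 values, 14 held 1 value far from the others, where chance alone marks about 1 in 20 groups, or 6.9. The groups are not independent, since several marked values came from the same library, so 14 is not a count of separate outliers. In the retina, the library of aged sham animal 16 stood apart with a pigment epithelium level of 4.89 log2 CPM (others 3.95 to 4.27) and with Myoc at 46.4 CPM (others 16.1 to 23.7), Ttr at 329 (93.3 to 134), Rgr at 126 (42.9 to 62), Pon1 at 9.47 (2.43 to 3.64) and Rpe65 at 58.6 (18.5 to 24.6). Aged OVX animal 19 had a pigment epithelium level of 4.05 (others 3.64 to 3.75), young sham animal 5 had Ttr at 148 CPM (54.5 to 87.9), young OVX animal 12 had Pon1 at 2.05 (3.74 to 4.74) and young sham animal 4 had a rod level of 10.5 (10.7 to 10.8). The retina library of young OVX animal 9 held 30.74 M counts (others 15 to 19.89 M). In the posterior eye, aged OVX animal 20 had a cholesterol list level of 6.05 (6.32 to 6.46), and the sebaceous gland level was 3.46 in young OVX animal 10 (0.238 to 1.05) and 6.49 in aged sham animal 16 (0.098 to 1.29).

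The other marked results were differences between ages or tissues that passed a test of the difference itself. In the retina the interaction of OVX and age was -2.758 for Myoc, -2.355 for Rgr, -2.42 for Ttr, -2.517 for Pon1 and -2.091 for Rpe65 on the log2 scale, and the median over the pigment epithelium list was -0.867. For Gnaq the OVX effect in the posterior eye exceeded that in the retina by 0.4046.

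The pigment epithelium pattern in the retina was weighed against tissue carried along at dissection, in which case genes with the larger excess in the posterior eye should have the more negative interaction. Over the 24 genes of the list, which are not independent, the Spearman rho was -0.707, and 21 interactions lay below 0, which is consistent with carried-along pigment epithelium. Of 100 groupings of the libraries, the real one included, 1 gave the list a p as small (5.59e-21 against a smallest other of 4.36e-11), so a random grouping is an unlikely source, although the list was the strongest of 44 and its adjusted p with an estimated correlation was 0.0407, between 0.0115 and 0.0975 with 1 library left out. Tyr, with the largest excess (6.3), had an interaction of -0.653. A change of expression within the pigment epithelium itself was not separated from a change in its amount. Genes at similar levels in both tissues, such as Best1 (0.198) and Mertk (0.477), would shift little in the retina in either case. The rho therefore cannot tell the 2 apart.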

How the results depend on the processing

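The tests with the sebaceous gland column, alone or with the rod column, and without animals 1 and 10 were chosen only after the result was seen. RLE scaling and leaving out animals 22 and 23 kept every count of called genes within 1.5 times. With the animal as a replicate block, which pairs the tissues, 1 gene was called for the tissue difference, as without it, and the block changed no call. The numbers of called genes in the order OVX young, OVX aged, OVX mean, ageing in sham, ageing in OVX and interaction were 1, 0, 0, 0, 0 and 0 in the posterior eye and 3, 1, 8, 6, 11 and 7 in the retina with edgeR. DESeq2 called 10, 27, 67, 5, 93 and 0 in the posterior eye and 60, 9, 48, 59, 67 and 22 in the retina. Limma-voom called 1, 0, 4, 0, 75 and 0, and 9, 0, 13, 6, 30 and 9. With surrogate variables the counts were 0, 0, 0, 11, 272 and 0, and 0, 0, 87, 6, 20 and 11, of which 5, 2, 4 and 6 were shared for the last 4. Fitting only the groups compared gave 0 for young OVX and 1 for ageing in OVX in the posterior eye and 17 for ageing in OVX in the retina, 6 of them shared with the 11. In the retina it also called 3 genes for young OVX and 1 for aged OVX, with 0 shared, so Tfeb, Coq10b, Pfkp and Myoc lost their calls. Without the filter on low counts, 0 genes were called for young OVX in the retina, where more genes share the adjustment. With the rod column 6 were called for young OVX, 2 for the OVX mean and 1 for ageing in OVX in the posterior eye, and with the sebaceous gland column 0 for young OVX. With the pigment epithelium column 0, 0, 0 and 0 were called in the retina for young OVX, aged OVX, ageing in sham and the interaction, and 2 for ageing in OVX, 0 of them among the 11. For the OVX mean the same column gave 9, with 8 of 8 shared. For these differences the cause was not tested.

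With 1 library left out, counts ran from 1 to 2 for young OVX, 0 to 5 for the OVX mean and 0 to 1 for ageing in sham in the posterior eye. In the retina they ran from 0 to 4 for young OVX, 0 to 1 for aged OVX, 0 to 10 for the OVX mean, 0 to 24 for ageing in sham, 2 to 16 for ageing in OVX and 4 to 13 for the interaction. The matrix list had adjusted p from 0.0452 to 0.983 in aged OVX posterior eye, from 4.38e-06 to 0.0994 in young OVX retina, from 0.0248 to 0.925 in aged OVX retina and from 0.000149 to 0.0657 for the OVX mean in the retina.

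The matrix list lost its call with an estimated correlation in the posterior eye (adjusted p = 0.756 young, 0.678 mean) and the retina (0.677, 0.876), and with fry (0.808, 0.726, 0.563 and 0.734). With the pigment epithelium column the young retina gave 0.18. With the rod column the aged posterior eye gave 0.908. With rod and sebaceous gland columns together the matrix list gave 0.464 in young OVX, 0.215 in aged OVX and 0.951 for the OVX mean, the last with the direction turned. The same columns turned the direction for the OVX mean of elastic fibre genes (0.682), collagen processing genes (0.896), integrins (0.896), macrophage genes (0.951) and amacrine cell genes (0.896), and for cholesterol genes with age in sham (0.412; 0.186 with the sebaceous gland column alone). Ribosomal genes turned for the OVX mean with the sebaceous gland column (0.743), as did retinal melanocyte genes in aged OVX (0.969) and glucocorticoid response genes in the interaction (0.909) with the pigment epithelium column. The cause was not tested. Without animals 1 and 10, those highest in rod genes in their groups, 18 of 18 lists kept their direction and side of the threshold. With the spread of the posterior eye, changes under 2-fold were often missed in the simulated counts. In the real counts larger differences, such as that of Fos in young OVX, were also not called.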

Other observations

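The tests with the rod and sebaceous gland levels were chosen only after the result was seen. With age in sham animals, glucocorticoid targets lay higher in the posterior eye, where Zbtb16, a zinc finger repressor, was at 9.7 CPM in young and 18.1 in aged sham and Tsc22d3, an anti-inflammatory leucine zipper gene, at 189 and 278. Their list had 10 of 15 above 0 (adjusted p = 0.0269, 3 called when adjusted over the list alone; adjusted p = 0.889 with an estimated correlation). Per2, a clock repressor, was at 58.7 and 85.4 CPM. In the retina the same list had 11 of 15 above 0 (adjusted p = 0.0103, 5 called when adjusted over the list alone; adjusted p = 0.39 with an estimated correlation).

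Within the aged retina, heat shock and unfolded protein genes had 19 of 26 above 0 in OVX (median 0.0779, adjusted p = 0.00241; adjusted p = 0.798 with an estimated correlation), and the chaperone gene Hspa5 was at 308 CPM in sham and 344 in OVX. Blood genes had 4 of 5 below 0 (median -0.507, adjusted p = 0.00766, 3 called when adjusted over the list alone; adjusted p = 0.618 with an estimated correlation), with Hbb at 21.2 and 14.9 CPM. In the aged posterior eye proliferation genes had 23 of 25 above 0 (median 0.174, adjusted p = 1.9e-05; adjusted p = 0.944 with an estimated correlation), and Mcm2, a replication helicase subunit, was at 52.5 and 62.4 CPM.

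The counts of called genes were set against other groupings of the same libraries, 100 per contrast with the real one included. In the posterior eye 5 groupings called at least the 1 gene of young OVX (highest other 2029), and 100 called at least the 0 genes of aged OVX (2168), the OVX mean (1210), ageing in sham (4382), ageing in OVX (5) and the interaction (1483). Every grouping reaches a real count of 0, so the share of 100 is fixed in advance and tests nothing. In the retina 1 called at least the 3 genes of young OVX (highest other 1), 12 the 1 gene of aged OVX (616), 2 the 8 genes of the OVX mean (347), 2 the 6 genes of ageing in sham (91), 1 the 11 genes of ageing in OVX (0) and 3 the 7 genes of the interaction (119). For the tissue difference 3 of 40 groupings called at least 1 (highest other 3). Groupings that call many more genes than the real one may point to a structure of the samples, but which libraries they separate was not tested.

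Higher matrix genes in the young OVX posterior eye were weighed against tissue carried along. Of 100 groupings, 24 gave the list a camera p as small as the real 9.2e-08 (smallest other 1.19e-24), so the shift could arise from a grouping unrelated to surgery. Adding the rod level left the list called (adjusted p = 0.00358) with a median of 0.139, close to that without it. The rod level alone thus accounted for little of the shift. The list had an adjusted p = 0.756 with an estimated correlation before that, so the shift itself is uncertain and carried-over retina is not excluded. Adding rod and sebaceous gland levels together ended the call (adjusted p = 0.464, median 0.056), as a varying mix of tissues would. With group means removed, however, no relation of the matrix level was detected with either level. The Pearson r was -0.201 with the sebaceous gland level (permutation p = 0.507) and -0.154 with the rod level (permutation p = 0.484). A response of the matrix to loss of the ovaries was not separated from that mix.

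Lower cholesterol genes in the young OVX posterior eye were weighed against sebaceous gland tissue carried along. Of 100 groupings, the real one included, 2 gave a camera p as small as the real 1.12e-21 (smallest other 1.46e-29), but the list was the strongest of 44, which this count does not allow for. The mean level of the list differed by -0.46 log2 CPM (exact permutation p = 0.039, adjusted p = 0.371). Adding the sebaceous gland level left the list called by camera (adjusted p = 8.13e-10) with a median of -0.285 against -0.457 without it, but the list had an adjusted p = 0.397 with an estimated correlation, so carried-over gland stays open. After its slope on the sebaceous gland level (0.0966) was removed, the difference in mean level was -0.239 against -0.458 before (exact permutation p = 0.106), so a few gland-rich libraries and an effect of surgery cannot be told apart there.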
